A study of Homo sapiens with 6 samples.

How the data were processed

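Gene expression was measured on 6 Affymetrix whole-transcript arrays, each from one RNA sample of primary human corneal epithelial cells obtained from a commercial supplier. Per the labels' protocols, cells at an early passage were plated at 100000 cells per well onto transfection complexes with 30 nM siRNA and RNA was taken 72 hours later. The siRNA was either a scrambled control (3 arrays) or a mixture of 3 siRNAs against EHF (3 arrays). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

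The deposited value table holds linear intensities, 1 per probe set and array, for 33297 probe sets. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1.1 and PLIER 2.0, a model-based method that combines the probes of a probe set into 1 value. How background was corrected, whether and how the arrays were normalized to each other, and which genome build underlies the probe sets are not given in the sources used here. The values run down to nearly 0 on every array, which shows that no constant of 16 had been added before deposit. Median intensities per array ranged from 140.4 to 149.1. Arrays give no count of molecules, so the number of arrays and the brightness of a probe set over the background limit the precision, and no detection calls were used. A scaling step before deposit that left a trend with intensity would shift dim and bright genes differently between groups. This was examined through the olfactory receptor genes, a family assumed here to be mostly silent in these cells.

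Probe sets were named through the platform annotation. A single gene symbol was given for 19460 probe sets, several symbols for 1754 and none for 12083. Those with several symbols or none were left out of the gene-level analysis, so genes such as TP63, KRT17 and COL17A1 were not analysed here. Through Entrez identifiers, 19429 probe sets were matched to the RefSeq table of the GRCh38.p14 assembly, and 0 symbols had to be updated. That table served only for names and for the order of neighbouring genes, and no coordinates are printed because the build behind the probe sets is not stated. The brightest probe set over all 6 arrays stood for each of 18417 gene symbols. Close paralogs (the SPRR2 genes, S100A7 and S100A7A, SERPINB3 and SERPINB4, histones, mucins, metallothioneins) may share probes, and their values are uncertain to that extent. Y-linked genes and XIST are not reported.

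Values were analysed as log2(intensity + 16) with no further normalization and no filter on low values. Fold changes are on this scale, which understates the change of dim genes. A linear model with the siRNA group as its only term was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and two-sided p-values were adjusted by the Benjamini-Hochberg method over all 18417 genes. A gene was called at an adjusted p under 0.05, and a second count asked in addition for a log2 fold change of at least 1 in size. All signed values are EHF siRNA minus control siRNA.

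The design, the offset, the 32 gene lists, the rule for named genes and all alternatives except 3 were fixed before the data were examined. Of 703 list memberships, 652 were measured by a probe set with 1 symbol. The rule names EHF, then the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups do not overlap, and then up to 4 members of each list with the smallest p (at most 2 higher and 2 lower), or any called member of a list with at most 5 called members. Genes named outside the rule are said to be so. Lists were tested with limma's camera, which asks whether a list's genes rank apart from all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with a correlation estimated from these arrays and fry, which asks whether a list's genes moved on balance one way, were run beside it. The lists cover cornified envelope genes, corneal differentiation markers, limbal and basal markers, mucosal and stress keratins, mucins, tight junctions, desmosomes, hemidesmosomes, barrier lipids, kallikreins and serpins, antimicrobial and S100 genes, epithelial transcription factors, Kruppel-like factors, the ETS family, Notch signalling, EGF receptor signalling, DNA replication, mitosis, histones, p53 targets, interferon response, cytokines, epithelial-mesenchymal transition, matrix metalloproteinases, cholesterol synthesis, the unfolded protein response, glycolysis and hypoxia, and markers of stromal, endothelial, conjunctival, melanocytic and immune cells.

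The code was tested on simulated data before use: log2 values were drawn for all 18417 genes of the same comparison with 200 genes changed by known amounts. Of 50 genes changed by 0.25 on the log2 scale, 30% were recovered. The share was 74% at a change of 0.5 and 100% at changes of 1 and 2. Among 160 called genes, 8 were unchanged ones, and 1 list, the shifted one, was called. The simulated genes varied independently and had no shift of dim genes. In the real arrays the estimated correlation within a list reached 0.919, for the interferon response. The simulation therefore does not measure false calls of lists or genes under such correlation or shift. It also changed 200 genes, while 4041 were called in the real arrays. The Benjamini-Hochberg cutoff is looser when more genes change, so the recovered shares do not carry over to the real comparison.

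The alternatives were offsets of 1 and 64, quantile normalization, subtraction of each array's median, leaving out the dimmest 25% or 50% of genes, an intensity trend or robust estimation in eBayes, array quality weights, the mean of a gene's probe sets, every probe set tested separately, the replicate number as a block, leaving out each array in turn, camera with an estimated correlation, camera on ranks, and fry. Chosen after seeing the data were cyclic loess normalization, leaving out genes no brighter than the 95th percentile of olfactory receptor genes, and cyclic loess together with an estimated correlation. Gene annotation and figures were prepared with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.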

Results

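The data comprised 6 arrays of primary human corneal epithelial cells, 3 transfected with scrambled control siRNA and 3 with EHF siRNA, all harvested after 72 hours. EHF is an ETS-family transcription factor of epithelial cells, and the comparison asks which transcripts change when its own transcript is depleted. Expression profiles correlated at 0.9973 or more within a group across genes, while the highest correlation between groups was 0.9948, and no arrays were identical. Median array intensity lay at 142.1, 142.9 and 140.4 in control samples and at 148.5, 148.4 and 149.1 in EHF siRNA samples.

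EHF itself was reported first as a check of the labels. Its intensity was 5022.75, 4921.92 and 4970.95 in control replicates 1 to 3, and 1484.69, 1335.06 and 1141.58 in EHF siRNA replicates 1 to 3. On the log2 scale the mean was 12.28 ± 0.015 (SD, n = 3) in control and 10.38 ± 0.19 (SD, n = 3) in EHF siRNA samples, a 3.75-fold lower level (log2 fold change -1.91, SE 0.0855, limma adjusted p = 1.39e-05). All 3 EHF siRNA arrays lay below all 3 control arrays, so the labels and the targeted transcript matched.

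Depletion of EHF was accompanied by lower expression of part of the small proline-rich proteins, S100 alarmins, kallikreins, serpins, junction components and epithelial transcription factors, and by higher expression of POSTN, CXCL14, SLITRK6 and SLC7A8. The lower gene lists among these were called at a preset correlation between genes, and none was called with an estimated one (adjusted p = 0.439 to 0.505). Because a single mixture of EHF siRNAs was compared with a scrambled control, changes through EHF and other effects of the mixture cannot be told apart. MMP12, the macrophage elastase, showed the largest decrease at 6.11-fold (log2 fold change -2.61, SE 0.107, adjusted p = 1.39e-05), and POSTN, the matrix protein periostin, the largest increase at 3.47-fold (log2 fold change 1.79, SE 0.0837, adjusted p = 1.39e-05). The mean of MMP12 in EHF siRNA samples (6.50) lay below the 95th percentile of olfactory receptor genes (6.89). The size of its decrease therefore depends on the offset, from -2.84 with an offset of 1 to -2.11 with 64. Changes of at least 2-fold were mostly decreases, with 50 genes lower and 8 higher. At any size, 2322 genes were higher and 1719 lower of 18417 tested, but 3807 of these 4041 genes differed by less than 1.5-fold. The higher share of calls was 57.5%, against 48.4% after quantile normalization (1527 higher, 1630 lower) and 41.7% after cyclic loess (1281 higher, 1791 lower), and 0 genes were called in opposite directions. In 7814 genes (42.4%) the groups did not overlap, where chance gives 10% for 3 against 3.

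The excess of small increases lay among dim genes. The 338 olfactory receptor genes, assumed to be mostly silent in these cells, had a median log2 fold change of 0.0888. It was 0.0125 after cyclic loess, which removes such a trend by construction. Dimness went with the direction of calls: 32.2% of the genes called higher but 9.19% of those called lower were no brighter than the 95th percentile of that family. Of all 18417 genes, 5546 were no brighter than that. The share among higher calls was thus near that of all genes, and the share among lower calls below it. In the 3 dimmest of 10 equal bins by level, 123, 274 and 348 genes were higher and 32, 38 and 83 lower. After cyclic loess, 30, 49 and 101 were higher and 72, 71 and 159 lower. As deposited, more dim genes were thus called higher than lower, and after cyclic loess fewer. Among genes named below, CASP14, SPINK6, KLK14, DSG1, NID1, LIPK, ZEB2, DCN, CD34, OCA2, SLC45A2 and CSF1R lay below that level in both groups, and ERG, CCNE2 and COL3A1 in 1 group, so the sizes of their changes are uncertain. The number of calls also depended on single arrays: without EHF siRNA replicate 3 it was 838 higher and 874 lower, without control replicate 1 it was 1156 and 1061, and without EHF siRNA replicate 2 it was 1382 and 1139. Called without each array in turn, and after quantile normalization and cyclic loess, were 636 higher and 821 lower genes, including the 8 and 50 with changes of at least 2-fold; the count of 8 was 5 without control replicate 2 because some then fell short of 2-fold.

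**Figure D1:**
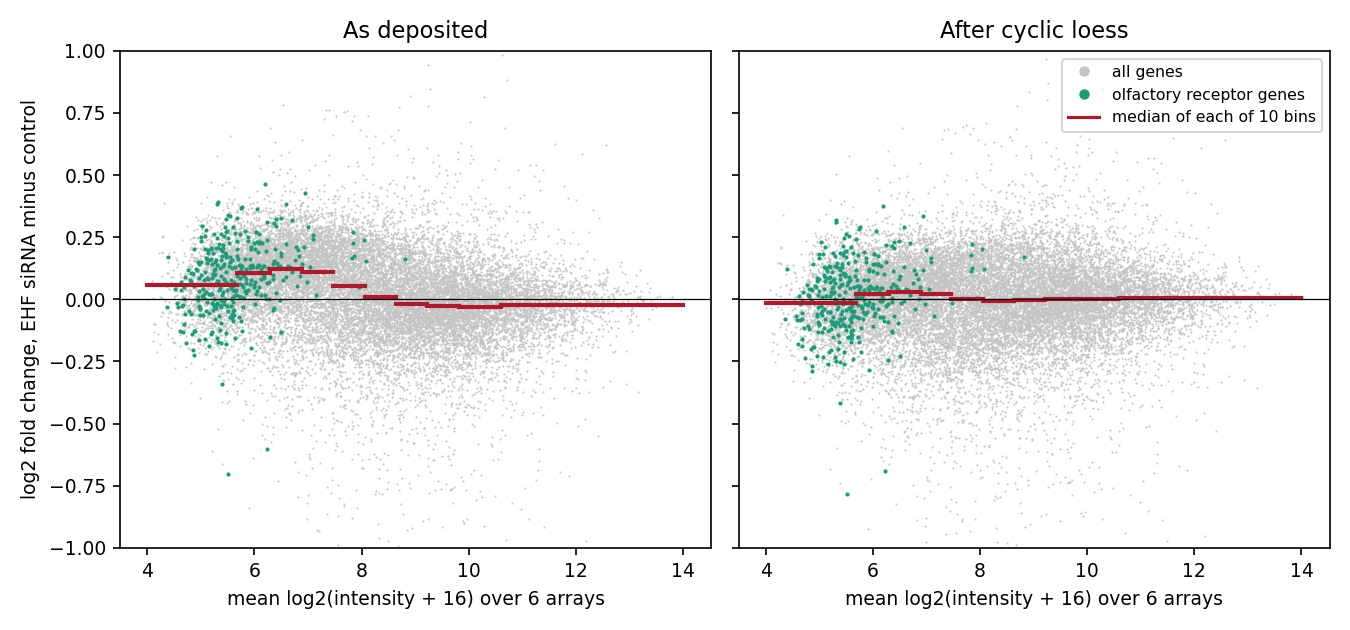
Log2 fold change (EHF siRNA minus control) against mean log2(intensity + 16) over 6 arrays, for values as deposited (left) and after cyclic loess (right); grey points are genes, green points olfactory receptor genes, and red bars the medians of 10 equal bins of genes by level. As deposited, the medians lie at 0.0591 to 0.121 in the 4 dimmest bins and at -0.0313 to -0.0171 in the 4 brightest, and 58 genes (left) and 62 genes (right) fall outside the plotted range of 1 in size.

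The 12 largest decreases included MMP12 and EHF itself, the siRNA target. PDZK1IP1, a small membrane-associated protein, was 3.91-fold lower (log2 fold change -1.97, SE 0.145, adjusted p = 0.000133). The cornified envelope precursors SPRR2E (-1.95), SPRR2B (-1.73) and SPRR2D (-1.64) fell as well, and as close paralogs they may share probes. TNFSF18, a ligand of the TNF family, fell 3.61-fold (-1.85, SE 0.0757), reaching an intensity of 43.8 ± 6.73 (SD, n = 3) in EHF siRNA samples. SERPINA3, a serine protease inhibitor of the acute phase (-1.64), TNIP3, an inhibitor of NF-kappaB signalling (-1.63), S100A7A (-1.56), IGFBP3, which binds insulin-like growth factors (-1.54), and CRABP2, which carries retinoic acid (-1.51), completed the set. Like MMP12, TNFSF18 (5.90), SERPINA3 (6.81) and CRABP2 (6.26) had EHF siRNA means below the 95th percentile of olfactory receptor genes. Their sizes depend on the offset too. The adjusted p of these 12 genes ranged from 1.39e-05 (MMP12) to 0.000397 (S100A7A).

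Rank by rank, the 12 largest increases were smaller than the decreases. After POSTN came CXCL14, a chemokine of epithelia (log2 fold change 1.40, SE 0.124, 2.64-fold, adjusted p = 0.000288), the membrane protein SLITRK6 (1.28), the amino acid transporter SLC7A8 (1.20), the cyclin CCNA1 (1.07), the glutathione peroxidase GPX2 (1.05), the secreted hormone STC1 (1.05) and the protease inhibitor TFPI2 (1.00). LPXN, a focal adhesion protein (0.98), the matrix protein THBS2 (0.94), the ERK phosphatase DUSP6 (0.88) and the alarmin cytokine IL33 (0.85) followed. Their adjusted p ranged from 1.39e-05 (POSTN) to 0.000959 (GPX2), and the 3 values of each group lay apart for every one of the 24 genes.

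**Figure D2:**
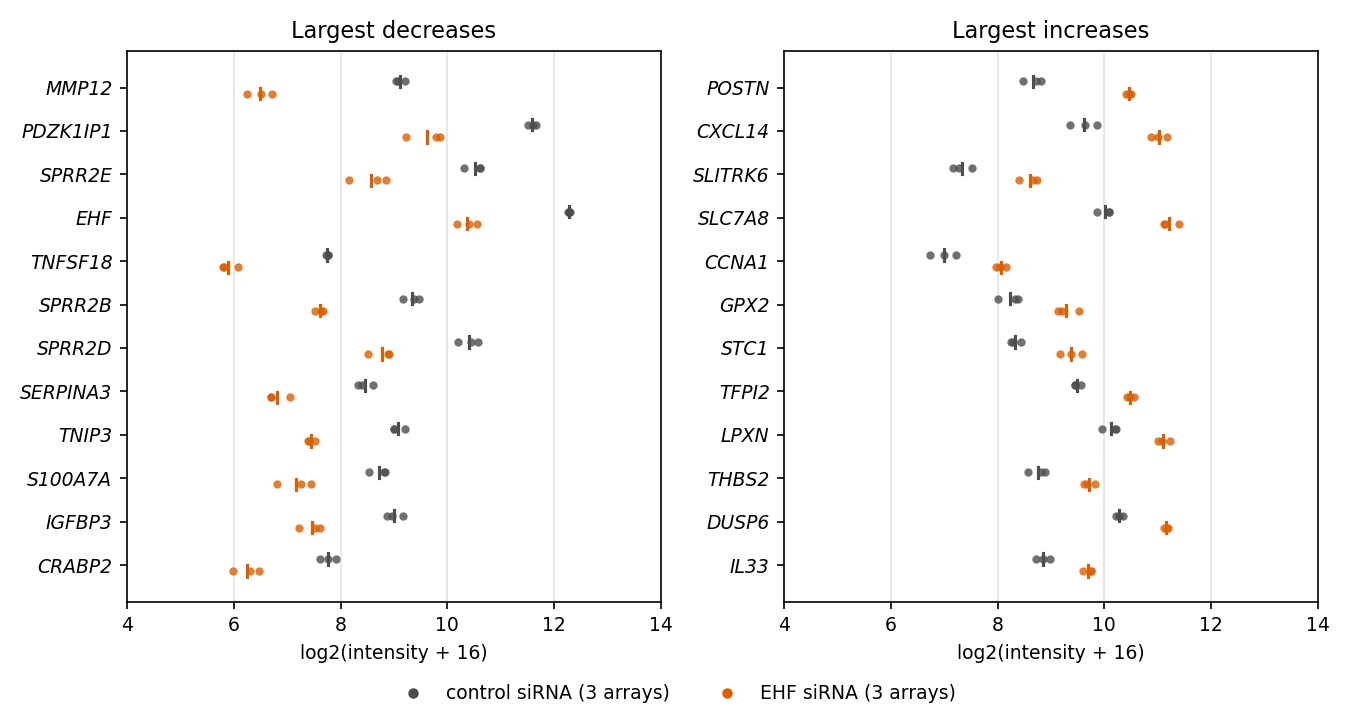
Log2(intensity + 16) on each of 6 arrays for the 12 genes with the largest decrease (left) and the 12 with the largest increase (right); grey points are control siRNA arrays, orange points EHF siRNA arrays, and vertical ticks the mean of each group (n = 3). MMP12 goes from a mean of 9.11 to 6.50 and POSTN from 8.67 to 10.46, and for each gene the groups are separate.

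Of the 32 gene lists, 11 ranked lower and 1 higher than other genes by camera at the preset correlation of 0.01. With a correlation estimated from the arrays, 0 lists were called by camera in either direction (2 of 32 had an unadjusted p under 0.05), while fry called 15. With so few arrays, camera with an estimated correlation can hardly call a list. Its lack of calls therefore neither upholds nor undoes those at the preset correlation. Called members, summed over the lists, numbered 249, and they were fewest without EHF siRNA replicate 3 (168) and control replicate 1 (180).

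Epidermal-type differentiation genes fell in part. Of 36 cornified envelope genes, 15 fell, 7 rose and 14 were not called (18 and 8 adjusted over the list alone), and the list ranked lower (camera adjusted p = 0.000188; adjusted p = 0.505 with an estimated correlation). The 3 most reduced were the SPRR2 genes named above, while the 7 higher members, among them CASP14 (0.23) and LCE3E (0.19), had small increases, and 1 of the 7, LCE3E, remained called after cyclic loess. The call of LCE3E ended without each of the 6 arrays in turn (adjusted p = 0.0511 to 0.0804). Another list joins kallikreins, which are proteases, with serpins and other protease inhibitors, genes that control shedding of surface cells. It had 16 of 23 members lower, 2 higher and 5 not called (17 and 2 adjusted over the list alone). Its camera adjusted p was 3.56e-10, and 0.439 with an estimated correlation. SERPINB13 fell 1.70-fold (-0.76, SE 0.0642) and the kallikrein KLK8 1.45-fold (-0.53, SE 0.0477), whereas the increases of SPINK6 (0.22) and KLK14 (0.19) were no longer called after cyclic loess. Among 11 mucosal and stress keratins, 6 fell and 5 were not called (6 lower and 2 higher adjusted over the list alone), with KRT23 at -0.74 and KRT7 at -0.38. The stress keratins KRT6A, KRT6B, KRT6C and KRT17 had no probe set with 1 symbol and were not analysed. The keratin list ranked lower (adjusted p = 0.0235; adjusted p = 0.505 with an estimated correlation), a call that ended after cyclic loess (adjusted p = 0.0799), after quantile normalization (adjusted p = 0.0836), without control replicate 2 (adjusted p = 0.0659) and without EHF siRNA replicate 1 (adjusted p = 0.0509). It also ended without the dimmest 25% of genes (adjusted p = 0.0756), the dimmer 50% (adjusted p = 0.0896) or genes at the olfactory receptor level (adjusted p = 0.0926), and by camera on ranks (adjusted p = 0.11). With 1 array left out, 13 to 16 cornified envelope genes were lower and 0 to 5 higher, the 0 without control replicate 1 and without EHF siRNA replicate 3. The list of kallikreins, serpins and protease inhibitors had 14 to 16 lower and 0 to 2 higher, and keratins 5 lower and 0 to 1 higher.

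Corneal identity markers were not called as a group. Of 17 corneal differentiation markers, 7 rose, 4 fell and 6 were not called (7 and 4 adjusted over the list alone; camera adjusted p = 0.935). After cyclic loess 3 were higher and 4 lower. The gap junction gene GJB6 (-0.62, adjusted p = 0.000169) and the transcription factor KLF4 (-0.52) fell, and the corneal crystallin ALDH3A1 (0.33) and the desmosomal cadherin DSG1 (0.52, below the olfactory receptor level in both groups) rose. Limbal and basal markers were also mixed, with 7 of 21 higher, 4 lower and 10 not called (8 and 5 adjusted over the list alone; adjusted p = 0.935): CXCL14 and TCF4 (0.43) rose, and WNT7A (-0.41) and the cadherin CDH3 (-0.35) fell. Barrier lipid genes had 4 of 21 members higher, 6 lower and 11 not called (5 and 9 adjusted over the list alone, 2 and 7 after cyclic loess; adjusted p = 0.136), including the ceramide synthase CERS3 at -0.44, the lipase LIPK at -0.54 and the desaturase DEGS2 at 0.28. That list was called lower without control replicate 3 (adjusted p = 0.0426), but not over all 6 arrays with an estimated correlation (camera adjusted p = 0.505). Leaving out 1 array gave 2 to 4 corneal differentiation markers higher and 3 to 4 lower. Limbal markers had 2 to 6 higher, with 2 without EHF siRNA replicate 3 and 4 without control replicate 1, and 3 to 4 lower. Barrier lipid genes had 1 to 3 higher and 5 to 6 lower.

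Part of the transcription factors of epithelial differentiation fell. Of 19 members, 8 fell, 2 rose and 9 were not called (9 and 2 adjusted over the list alone), and the list ranked lower (adjusted p = 0.000368; adjusted p = 0.450 with an estimated correlation). ZNF750, which drives epidermal differentiation, fell 2.29-fold (-1.19, SE 0.0776, adjusted p = 6.81e-05) and OVOL1, a repressor in the same lineage, 1.76-fold (-0.82, SE 0.0837), while the increases of BNC1 (0.20) and TRPS1 (0.17) ended when single arrays were left out. Of 14 Kruppel-like factors, KLF4 and KLF8 (-0.36) fell, KLF15 (0.43) rose and 11 were not called (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.597, with a mean of -0.026 and a median of 0.022). The call of KLF15 ended without control replicates 1 (adjusted p = 0.0522) and 3 (adjusted p = 0.054) and without EHF siRNA replicates 1 (adjusted p = 0.0551) and 3 (adjusted p = 0.0615). Of 24 other ETS-family members, 6 rose, 2 fell and 16 were not called (6 and 3 adjusted over the list alone; adjusted p = 0.669). FLI1 rose 1.68-fold (0.75, SE 0.0792) and GABPA 1.47-fold (0.55, SE 0.0591), and ERG (-0.36) and ETV3 (-0.21) fell. By fry the ETS list was called (adjusted p = 0.0225). With 1 array left out, 5 to 7 epithelial transcription factors were lower, with 5 without control replicate 1 and without EHF siRNA replicate 3, and 0 to 1 higher. Kruppel-like factors had 2 lower and 0 to 1 higher, and ETS members 6 to 7 higher and 2 to 4 lower, the 4 without EHF siRNA replicate 1.

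Part of the junction and glycocalyx genes fell. Desmosome and adherens junction genes had 9 of 19 members lower, 2 higher and 8 not called (9 and 2 adjusted over the list alone; camera adjusted p = 5.12e-05; adjusted p = 0.450 with an estimated correlation). NECTIN4, an adherens junction protein, fell 2.02-fold (-1.01, SE 0.0798) and the desmocollin DSC2 1.64-fold (-0.71, SE 0.0552), while DSG1 of the same list rose. Tight junction and polarity genes had 9 of 23 lower, 1 higher and 13 not called (10 and 2 adjusted over the list alone; adjusted p = 0.0017; adjusted p = 0.439 with an estimated correlation), with the claudin CLDN7 at -0.76 and the membrane protease PRSS8 at -0.46. Of 17 mucin and glycocalyx genes, 8 fell and 9 were not called (10 lower and 1 higher adjusted over the list alone; adjusted p = 4.83e-05; adjusted p = 0.439 with an estimated correlation). The membrane mucins MUC1 (-0.74, 1.67-fold) and MUC20 (-0.52, 1.43-fold) fell, and mucins may share probes. Hemidesmosome and basement membrane genes were not called as a list, with 3 of 17 higher, 2 lower and 12 not called (4 and 2 adjusted over the list alone; adjusted p = 0.935), although the proteoglycan HSPG2 fell (-0.43). Nidogen NID1 was called higher (0.38) at a level below the olfactory receptor genes in both groups. Desmosome and adherens junction genes had 4 lower without control replicates 1 and 2 and without EHF siRNA replicate 3, 5 to 7 without the others, and 1 higher in each case. Tight junction genes had 6 to 8 lower and 0 to 1 higher with 1 array left out. Mucin and glycocalyx genes had 5 lower without control replicates 1 and 2 and EHF siRNA replicates 2 and 3, and 7 to 8 without the others. Hemidesmosome genes had 1 higher and 1 to 2 lower.

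Most antimicrobial and S100 alarmin genes fell, and their list had the lowest mean of the 32. Of 17 antimicrobial and S100 alarmin genes, 13 fell, 4 were not called and 0 rose (14 lower and 0 higher adjusted over the list alone), with a mean log2 fold change of -0.53 (camera adjusted p = 3.56e-10; adjusted p = 0.439 with an estimated correlation). The antimicrobial alarmin S100A7 fell 2.26-fold (-1.18, SE 0.0888) and the chemokine CCL20 2.14-fold (-1.10, SE 0.1). S100A7 and S100A7A, named above, may share probes. Inflammatory cytokines were split, with 7 of 28 higher, 8 lower and 13 not called (7 and 8 adjusted over the list alone; adjusted p = 0.362): IL33 and IL24 (0.45) rose, and ICAM1 (-0.42) and the interleukin-1 receptor antagonist IL1RN (-0.50) fell. The 34 interferon response genes ranked lower (mean -0.17, adjusted p = 0.000168; adjusted p = 0.773 with an estimated correlation), yet 1 gene fell, IFIT2 (-0.37, adjusted p = 0.0405), and 33 were not called (0 and 0 adjusted over the list alone, and 7 with an unadjusted limma p under 0.05). IFIT2 was no longer called after cyclic loess. Their mean log2 level was 10.92 on EHF siRNA replicate 1, above the control arrays at 10.79 to 10.88, and 10.60 and 10.46 on replicates 2 and 3. By fry, the interferon list was not called (adjusted p = 0.389). Without EHF siRNA replicate 1, 22 of the interferon genes were called lower, and without each other array 0 were. Antimicrobial genes had 10 to 13 lower with 1 array left out, and cytokine genes 5 to 8 higher and 7 to 8 lower.

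EGF receptor signalling genes rose more often than they fell, and Notch genes were mixed. Of 18 genes of EGF receptor signalling, 7 rose, 2 fell and 9 were not called (8 and 2 adjusted over the list alone; camera adjusted p = 0.091). The call was reached after cyclic loess (adjusted p = 0.0236) and quantile normalization (adjusted p = 0.0337). It was not reached with an estimated correlation (adjusted p = 0.450, and 0.492 after cyclic loess). The phosphatase DUSP6 and the ligand EREG (0.52, SE 0.0467) rose, while the receptor ERBB3 (-0.38) and the ligand EPGN (-0.34) fell. Of 19 Notch genes, 3 rose, 2 fell and 14 were not called (5 and 2 adjusted over the list alone, 2 and 3 after cyclic loess; adjusted p = 0.935), with the ligand JAG1 higher (0.54) and the receptors NOTCH3 (-0.77, 1.71-fold) and NOTCH2 (-0.39) lower. With 1 array left out, 6 to 7 EGF receptor signalling genes were higher and 2 lower, and 2 Notch genes were lower and 1 to 3 higher, the 1 without EHF siRNA replicate 3.

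Few proliferation genes were called. Of 34 mitotic genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, and 6 with an unadjusted p under 0.05), and 2 were lower after cyclic loess. Their list was not called (camera adjusted p = 0.091), but it was called lower without control replicate 2 (adjusted p = 0.0245), without EHF siRNA replicate 2 (adjusted p = 0.0399) and by camera on ranks (adjusted p = 0.0336). With an estimated correlation over all 6 arrays, the camera adjusted p of the mitotic list was 0.793. Of 29 replication genes, the cyclin CCNE2 (-0.60) and GINS3 (-0.31) fell, FEN1 (0.16) was higher by a margin that ended when single arrays were left out, and 26 were not called (2 lower and 0 higher adjusted over the list alone; adjusted p = 0.666, with a mean of -0.019 and a median of 0.032). Histone genes ranked lower, with 5 of 13 lower, 0 higher and 8 not called (7 and 0 adjusted over the list alone; adjusted p = 0.000917; adjusted p = 0.439 with an estimated correlation), including H4C8 at -0.53 and H2BC5 at -0.29, and they may share probes. Of 21 p53 targets, 2 rose, 2 fell and 17 were not called (2 and 2 adjusted over the list alone; adjusted p = 0.935), with DDB2, a DNA repair protein, at 0.40 and the cell cycle inhibitor CDKN1A at -0.37. Without control replicates 1 and 2 and EHF siRNA replicates 2 and 3, 1 p53 target was higher and 1 lower, and without the others 3 were higher and 2 lower. Histone genes had 3 to 7 lower with 1 array left out, with 3 without control replicate 1 and without EHF siRNA replicate 3. Replication genes then had 2 lower and 0 higher, and mitotic genes 0 to 1 in each direction.

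Matrix genes went both ways. Matrix metalloproteinases and their inhibitors had 4 of 21 higher, 5 lower and 12 not called (6 and 5 adjusted over the list alone; camera adjusted p = 0.276), and by fry the list was called (adjusted p = 0.00772). Beside MMP12, the tissue plasminogen activator PLAT fell 2.35-fold (-1.23, SE 0.0579, adjusted p = 1.39e-05), and MMP28 rose 1.41-fold (0.50, SE 0.0551). Epithelial-mesenchymal transition genes had 6 of 22 higher, 6 lower and 10 not called (7 and 6 adjusted over the list alone; adjusted p = 0.935, with a mean of 0.0023, a median of 0.045 and a camera direction downward). Fibronectin FN1 rose 1.54-fold (0.62, SE 0.0435) and the matricellular proteins CCN1 (-0.56) and TNC (-0.48) fell. ZEB2, an EMT regulator near background, was called higher (0.31), but not with the mean of all its probe sets (0.15, adjusted p = 0.0675). With 1 array left out, 2 to 3 metalloproteinase genes were higher and 5 to 6 lower, and transition genes had 5 to 6 in each direction.

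Part of the markers of stromal keratocytes and fibroblasts were higher. Of 18 members, 5 rose, 0 fell and 13 were not called (6 and 0 adjusted over the list alone), and the list ranked higher (adjusted p = 0.00551, and 0.0246 after cyclic loess; adjusted p = 0.439 with an estimated correlation). POSTN, THY1 (0.68), DCN (0.63), CD34 (0.40) and COL3A1 (0.28) rose, whereas COL1A1 (-0.04, adjusted p = 0.533) and KERA (-0.06, adjusted p = 0.481) were not called. Corneal endothelial markers had 2 of 10 higher, 2 lower and 6 not called (7 and 2 adjusted over the list alone; adjusted p = 0.209), with the collagen COL8A1 at 0.72 and the transporter SLC4A11 at -0.76. Conjunctival and goblet cell markers had 2 of 13 higher, 4 lower and 7 not called (4 and 4 adjusted over the list alone; adjusted p = 0.935, with a mean of -0.032 and a median of 0.12), with the water channel AQP3 at -0.70, S100A9 at -0.55 and the ETS factor SPDEF at 0.32. Melanocyte markers had 3 of 11 higher, 1 lower and 7 not called (5 and 1 adjusted over the list alone; adjusted p = 0.134), of which OCA2 (0.24) and SLC45A2 (0.31) were no longer called after cyclic loess. Each of the 3, the third being SOX10, lost its call without EHF siRNA replicate 2 (adjusted p = 0.0864 to 0.107) and without replicate 3 (0.0898 to 0.131). Immune cell markers had 2 of 14 higher, 1 lower and 11 not called (3 and 1 adjusted over the list alone; adjusted p = 0.935, with a mean and median above 0 and a camera direction downward), with CSF1R at -0.30. With 1 array left out, stromal markers had 5 to 6 higher, endothelial markers 1 to 3 higher and 1 to 2 lower, and conjunctival markers 1 to 2 higher and 3 lower. Melanocyte markers had 0 to 2 higher and 0 to 1 lower, and immune markers 0 to 3 higher and 1 lower. By fry the endothelial list was called (adjusted p = 0.0152).

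Most stress and metabolic genes were not called. The unfolded protein response list had 3 of 23 higher, 6 lower and 14 not called (3 and 7 adjusted over the list alone) and ranked lower (adjusted p = 0.0112; adjusted p = 0.450 with an estimated correlation), a call that ended after cyclic loess (adjusted p = 0.0799) and quantile normalization (adjusted p = 0.0836). It also ended without the dimmest 25% of genes (adjusted p = 0.0603), the dimmer 50% (adjusted p = 0.637) or genes at the olfactory receptor level (adjusted p = 0.0826). The stress factors ATF3 (-0.65) and DDIT3 (-0.43) fell, and the pseudokinase TRIB3 (0.46) and the disulfide isomerase PDIA4 (0.36) rose. Of 26 glycolysis and hypoxia genes, 2 rose, 4 fell and 20 were not called (2 and 4 adjusted over the list alone; adjusted p = 0.597, with a mean of -0.0054 and a median of 0.010), with the angiogenic factor VEGFA at 0.38 and the hexokinase HK1 at -0.29. Of 19 cholesterol synthesis genes, 3 fell and 16 were not called (3 lower and 0 higher adjusted over the list alone; adjusted p = 0.234), led by the sterol sensor partner INSIG1 at -0.26. Without control replicates 1 and 2 and EHF siRNA replicates 1 and 3, 1 of these genes was lower, and HMGCS1 was no longer called after cyclic loess (adjusted p = 0.0553). The unfolded protein response list had 3 higher and 5 to 6 lower with 1 array left out. Glycolysis genes had 1 to 2 higher and 4 lower, or 2 lower without EHF siRNA replicate 3.

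**Figure D3:**
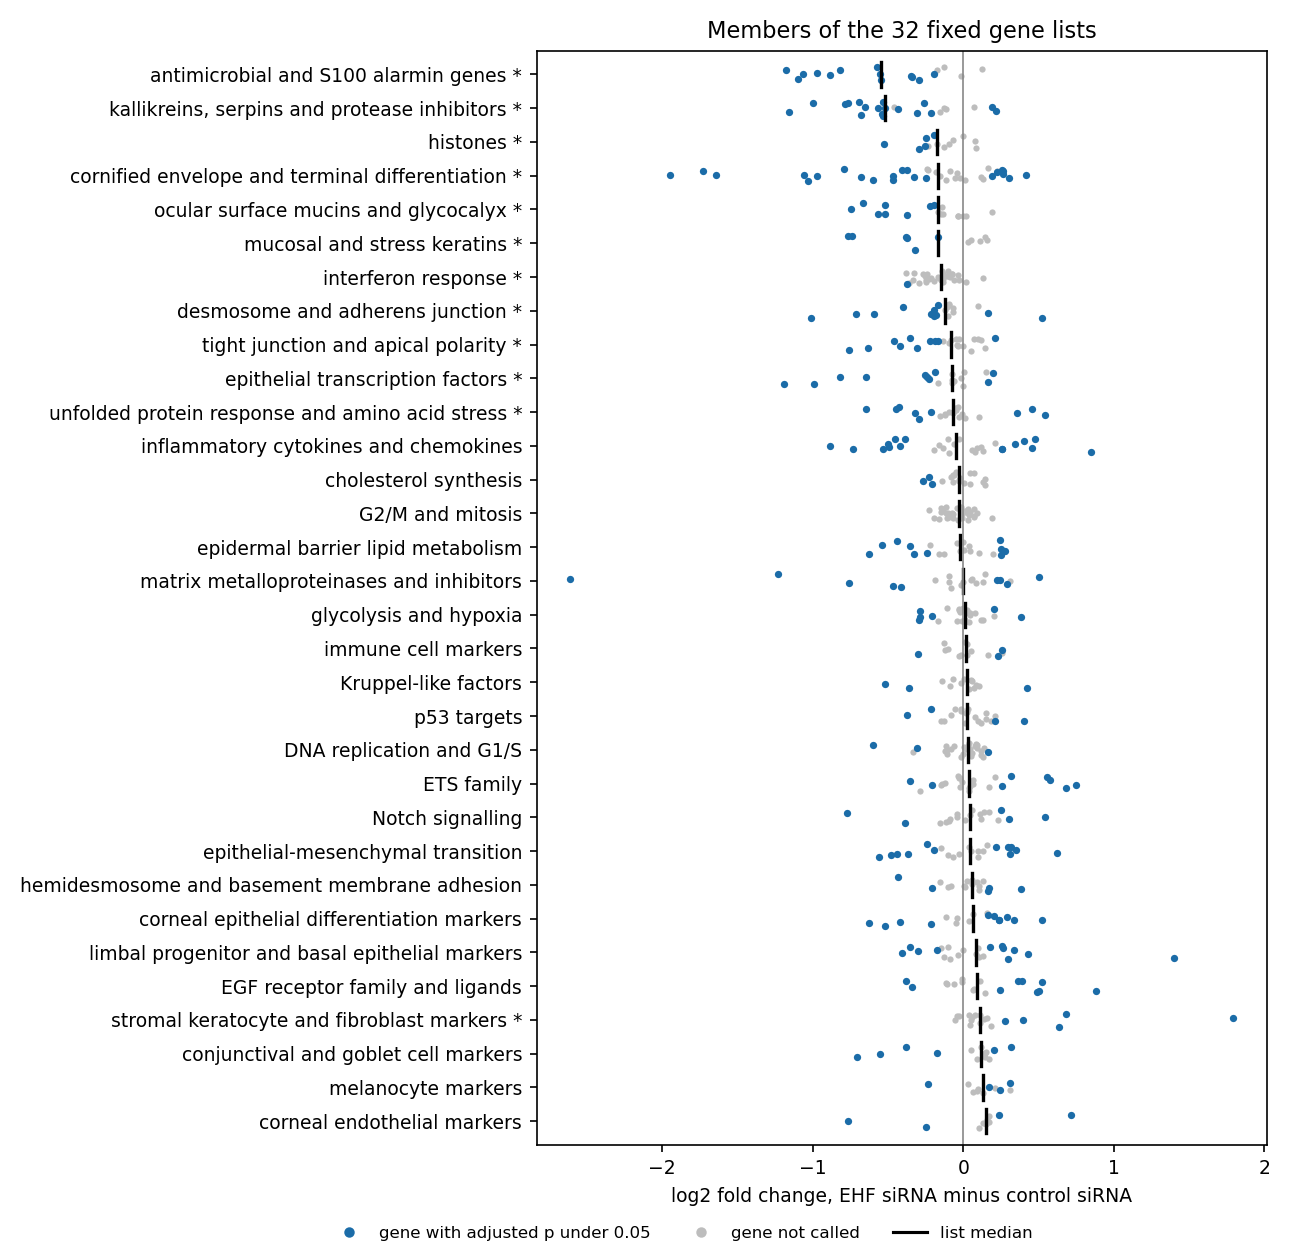
Log2 fold change (EHF siRNA minus control) of every measured member of the 32 gene lists; blue points are genes called over all genes, grey points genes not called, black bars list medians, and an asterisk marks lists called by camera at the preset correlation. Medians run from -0.55 for antimicrobial and S100 alarmin genes to 0.15 for corneal endothelial markers.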

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

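Cyclic loess, the limit at the level of olfactory receptor genes and cyclic loess with an estimated correlation were chosen after seeing the data; the other alternatives were fixed in advance. EHF stayed lower and called under all 19 alternatives that gave it a value (log2 fold change -2.00 to -1.81), and the other 23 genes with the largest changes were called under each alternative that kept them in the test. The size of the largest changes depended on the offset for dim genes: MMP12 went from -2.84 with an offset of 1 to -2.11 with 64, and TNFSF18 from -2.17 to -1.29. No result changed its direction past the threshold.

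Leaving out 1 array at a time gave 838 to 1866 genes higher, 874 to 1510 lower, 5 to 9 higher and 38 to 60 lower by at least 2-fold, an EHF change of -2.00 to -1.81, and 1 list higher in each case with 10 to 12 lower; the lowest counts of all calls came without EHF siRNA replicate 3, and fewer samples alone widen the errors. Of 129 called genes named by the rule, 95 kept their call without each array, and 34, none with a log2 change above 0.426 in size, did not; 17 calls ended after quantile normalization or cyclic loess.

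Genes higher numbered 1527 after quantile normalization, 1281 after cyclic loess, 1192 without the dimmer 50% of genes (9208 genes tested) and 1119 over all 33297 probe sets. The first pair goes with the shift of dim genes weighed under the other observations; the last pair tested other sets of features. Changes of at least 2-fold numbered 4 higher and 33 lower with an offset of 64, which by construction shrinks dim genes, and 32 lower without the dimmer 50%, which removes them. Lists called higher numbered 2 after quantile normalization, after cyclic loess, with an intensity trend, without the dimmer 50% of genes and without genes at the level of olfactory receptors (EGF receptor signalling was added each time; adjusted p = 0.0159 to 0.0493), and 4 by fry. With an estimated correlation 0 lists were higher and 0 lower, before and after cyclic loess. The loss of a call need not come from a high correlation between genes. For the stromal list the estimate was -0.00575, below the preset 0.01, yet its camera adjusted p went from 0.00551 to 0.439. For the other lists the part played by correlation was not tested separately. With an estimated correlation, camera takes its degrees of freedom from the arrays, which are few, rather than from the genes. The smallest unadjusted camera p of any list was then 0.0275. These p-values therefore cannot decide whether correlation between genes accounts for the calls made at the preset value. Robust estimation has no counterpart in camera, so its list values equal those reported.

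Replicate numbers showed no strong pairing of the samples: deviations of same-numbered arrays from their group means correlated at 0.0111, 0.048 and 0.114 across genes. Such weak correlations cannot tell whether same-numbered samples shared a culture, which the labels do not say. With the replicate number as a block, 2144 genes were higher and 1554 lower, 8 and 50 by at least 2-fold, and 1 list was higher and 11 lower. Signal over background limits the dim genes most, since the 95th percentile of olfactory receptor genes lay at a log2 level of 6.89 and 5546 genes were at or below it.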

Other observations

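The tests of the olfactory receptor median, of the interferon list, of stromal cells and of the stromal list after cyclic loess were chosen only after the result was seen, as were the genes named in the next paragraph.

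Some genes outside the lists were picked from the values for their size and are given without a claim about their classes. ALOX5 (log2 fold change -1.25, SE 0.0588, limma adjusted p = 1.39e-05) and its activating protein ALOX5AP (-1.40, SE 0.0627), which together start leukotriene synthesis, both fell. The serum amyloid genes SAA1 (-1.26) and SAA2 (-1.23) fell, and as close paralogs they may share probes. The transmembrane serine proteases TMPRSS11D (-1.10), TMPRSS11E (-0.96) and TMPRSS11F (-1.19) fell, while TMPRSS11B (-0.14, adjusted p = 0.201) was not called. ALOX5 (6.10) and ALOX5AP (6.81) had EHF siRNA means below the 95th percentile of olfactory receptor genes, so their sizes depend on the offset. Metallothioneins were uneven: MT1H (-1.41) and MT1M (-1.27) fell, whereas MT1E (0.030) and MT2A (0.0026) were not called, and members of this family may share probes. After cyclic loess each of these genes kept its sign, and the same ones were called.

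All gene families with at least 5 members sharing a symbol stem were tested with camera, 644 in number. The SPRR family had 8 of 10 members lower (adjusted p = 1.21e-07, and 2.24e-07 after cyclic loess) and the S100A family 9 of 16 (adjusted p = 0.000146, and 0.00169 after cyclic loess). The KRTAP5 keratin-associated genes had 7 of 11 higher (adjusted p = 0.00936, and 0.0188 after cyclic loess). Of 7 families called, these 3 were called after cyclic loess as well, and 4 were not: SYT (adjusted p = 0.00456, and 0.0619 after it), VPS (0.00936 and 0.223), LINC (0.00936 and 0.425) and EXOC (0.0318 and 0.136). Called only after cyclic loess were ZNF (0.0719 before, 0.00278 after), KLK (0.0859 and 0.0283) and SNORD (0.104 and 0.0485). With an estimated correlation 0 families were called (adjusted p = 0.817 for each of those named). With so few arrays that version of camera can hardly call a family, so its lack of calls decides nothing. The SPRR and S100A genes lie in 1 genomic neighbourhood, where 17 of 27 were lower and 0 higher. A change of that whole neighbourhood was tested on its 33 other measured genes: 12.1% were lower against 9.25% of genes elsewhere (Fisher's exact test, two-sided p = 0.542). No clear excess of lower calls was thus found among these neighbours. Of the 33, 12 were higher, against 2322 of all 18417 genes. These counts are for values as deposited, where the shift of dim genes can add higher calls. They include genes of any brightness, and dim ones cannot show a loss, so a shared loss across the region is not excluded.

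Dim genes were higher in EHF siRNA samples. A single deviating array was argued against, because all 3 EHF siRNA arrays had a higher median olfactory receptor level than every control array. Olfactory receptor genes had a median log2 fold change of 0.0888, so the shift reached genes assumed to be mostly silent in these cells. An intensity-dependent shift left by the processing before deposit and a difference in RNA yield or in the cells cannot be told apart, since the shift coincides with the groups. Its removal by cyclic loess decides nothing, because that method takes out such a trend whatever its source.

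The interferon list was lower on 2 of 3 EHF siRNA arrays. An effect present in every replicate is argued against, since replicate 1 had a list mean of 10.92 and only those 2 lay below the lowest control array at 10.79. Variation between arrays within the EHF siRNA group may account for it: the list means spanned 0.46 on the log2 scale within that group and 0.0843 within the control group, against a difference of 0.17 between the groups. Without EHF siRNA replicate 1, 22 of the 34 members were called lower, and without each other array 0 were. What differed between those wells was not tested.

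The stromal list was higher in EHF siRNA samples, and of its 18 members 8 lay above the olfactory receptor level in control cells and 0 were in another list. The shift of dim genes as the whole cause is argued against for its 5 called members, since all 5 stayed called after cyclic loess. Of these, DCN and CD34 lay below the olfactory receptor level in both groups. The list too was still called (camera adjusted p = 0.0246, mean log2 fold change 0.20 against 0.26 before). Its median fell from 0.112 to 0.0534, however, and the mean includes POSTN (1.79 before, 1.82 after), the largest increase of all genes. For the other members the shift stays open. The list was not called with an estimated correlation (adjusted p = 0.439, and 0.492 after cyclic loess). More stromal cells stay open: COL1A1, COL1A2, COL3A1, COL6A3, LUM and FBLN1 had a median log2 fold change of 0.0949 against 1.79 for POSTN. Of these 6, 3 were not above the olfactory receptor level in control cells, where an increase could be hidden. A response of the epithelial cells stays open as well.

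The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4041 called genes and 58 at 2-fold or more, the highest of the others gave 0 and 0, and 1 of 10 splits reached the real value in each case. Each other split had arrays of both siRNA groups on each side, which adds any difference between the groups to the spread within a side. Their counts of 0 therefore do not show how many calls chance gives.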
